A study of Mus musculus with 12 samples.

How the data were processed

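RNA abundance was measured in cell suspensions of the mouse thymus with Affymetrix 3'-end expression arrays, after extraction of total RNA and biotin labelling of the target, per the labels' protocols. The labels place 8 arrays in the group of leukemic cells from TEL-JAK2 mice and 4 arrays in the group of thymocytes from wild-type mice. Most titles carry what reads as an animal number, and nothing else says that the arrays come from separate animals, so p-values measure the spread between these samples. The number of arrays limits the precision of every value.

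The deposited values are intensities per probe set on a linear scale, 1 per array, made by the authors with RMA, per the submitters' processing notes. The version of RMA and any later step are not given in the sources used here. All intensities were above 0, and the array medians lay between 66.48 and 70.18, so the values were converted to log2 without an offset or further normalization. The table held 12488 probe sets, of which 66 were Affymetrix controls and 12422 were tested. The platform annotation gave 1 gene for 10833 probe sets, several for 396 and none for 1193. Of the probe sets with 1 gene, 10817 had that gene in a RefSeq table of the assembly GRCm38.p6, which served only for names and chromosome membership. The genome build behind the array annotation is not given in the sources used here, and no coordinates are reported. The 8251 genes were each represented by the probe set with the highest mean over all 12 arrays, a choice that does not look at the groups. There were 2073 genes with more than 1 probe set, and no gene had probe sets past the threshold in opposite directions. Gzma, Khdc1c, Fas, Jak3, Zfp36, Aldoa, Itgb1 and Pkm have only probe sets whose names mark possible cross-hybridization.

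Groups were compared on the log2 scale with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, no covariate), two-sided, at a Benjamini-Hochberg adjusted p under 0.05 over all probe sets or all genes. Every adjusted p for a gene or probe set comes from this limma model. Gene lists were tested with limma's camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over 38 lists. The lists named 667 genes, of which 545 were analysed. They comprise 14 lists of markers of other cells, 22 of biological processes, and 2 on sample quality. Genes held by several lists were kept in each. The spread between arrays was taken as the root mean square log2 difference of each array from the mean of the other arrays of its group, and compared with an exact permutation test. That test shuffled the finished distances and did not compute them anew for each assignment. T-cell receptor variable segments were described per array without a test. Chromosome-wide shifts, over genes above the median brightness, were compared with 10000 shuffles of genes over chromosomes. The background level was taken from 19 control probe sets for non-mouse transcripts, and a gene was called near the control level where both group means lay below the 95th percentile of these controls. Where this held for 1 group only, a fold is given as a lower bound ("at least"), from the mean of the brighter group to the mean, over the arrays of the dimmer group, of the higher of the array's control percentile and its own value. The log2 changes and their tests use the measured values.

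Genes named in the text follow a rule. It takes the fusion partners Jak2 and Etv6. It takes the 12 largest increases and the 12 largest decreases among changed genes whose leukemia arrays all lie above, or all below, every thymocyte array, without receptor segments and clone names. It takes up to 4 members with the largest moderated statistic in each biological or quality list, and up to 2 of the brightest members of each list of other-cell markers with any member changed at least 2-fold. Other members of the lists, and the genes of the closing section, were named after their values were seen. The groups, the designs, this rule, the lists and the first set of alternatives were fixed before the data were examined.

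These alternatives were the brighter part of the probe sets, quantile normalization, centring of arrays, trend and robust variance, array weights with a variance per group, leaving out each array in turn, arrays with a title number of 4 digits alone, an exact rank-sum test, an adjusted p under 0.01, limma's treat against a 1.5-fold change, no cross-hybridizing probe sets, the mean of all probe sets of a gene, camera with an estimated correlation, fry, and members of only 1 list. Others covered the spread, the segments and the chromosomes. A block for title numbers with and without 4 digits, the arrays without such a number alone, the macrophage marker score as a covariate, and the spread within the arrays with a 4-digit number were chosen after seeing the data, and so were the correlations of list scores across leukemias and the exact permutation test of list scores. The title number stands for a possible batch, since no scan date or other batch is used here.

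The limma and camera steps were tested on simulated data for the comparison of leukemia with thymocytes over 8251 genes. They recovered 82% of genes changed 1.5-fold, 96% at 2-fold, 100% at 4-fold and 98% at 8-fold, with 11 false calls. Both shifted lists were called, and 0 of the 36 other lists. The simulated genes varied independently of each other and equally in both groups. In the data the mitosis list had an estimated correlation of 0.603. The simulation therefore does not show how often lists are called wrongly in the data. Tables were prepared with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and plots were drawn with matplotlib 3.10.9.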

Results

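Gene expression was measured in the thymus of C57BL/6 mice on 12 arrays. Of these, 8 held leukemic cells of terminally ill mice with TEL-JAK2, a fusion that joins the transcription factor TEL (Etv6) to the tyrosine kinase Jak2, and 4 held thymocytes of wild-type mice aged 2 months. The arrays had closely similar brightness, with median intensities from 66.48 to 70.18 and highest intensities from 13334 to 16731. Between 57.6% and 64.0% of probe sets lay above the 95th percentile of the non-mouse controls of their array. Pairs of thymocyte arrays correlated at 0.990 to 0.997 over probe sets, pairs of leukemias at 0.961 to 0.993, and pairs across the groups at 0.955 to 0.980. No arrays were identical. The first principal component carried 46.5% of the variance, the second 19.7% and the third 13.3%.

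The main comparison asked which genes differ between TEL-JAK2 leukemic cells and normal thymocytes. The largest measured increases were those of Drc1, a subunit of the dynein regulatory complex of cilia (probe set 92377_at), and of the unconventional myosin Myo6 (92382_at), at least 31.6-fold and 33.5-fold, since their thymocyte means lay below the 95th percentile of the control probe sets. On the log2 scale Drc1 went from 5.00 ± 0.19 (SD, n = 4) in thymocytes to 10.33 ± 0.71 (SD, n = 8) in leukemias, and Myo6 from 5.32 ± 0.15 to 10.49 ± 0.76. Gldc, the glycine decarboxylase of the glycine cleavage system, rose 14.5-fold, the granule protease Gzma 12.7-fold and the myosin light chain gene Myl10 12.2-fold. Socs2, a cytokine-induced inhibitor of JAK-STAT signalling, rose at least 9.88-fold (measured log2 change 3.48, SE 0.15, adjusted p = 3.4e-08), and the inhibitory receptor gene Ctla4 at least 4.92-fold (3.25, SE 0.22), both from thymocyte means below that percentile. Khdc1c (log2 change 3.24), Mdfic (3.20), Pld4 (2.99), the calcium-binding protein gene S100a6 (2.99) and Plac8 (2.55) also rose.

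The largest decrease was that of the transcriptional repressor Bcl6 (103015_at), whose log2 value was 8.67 ± 0.19 (SD, n = 4) in thymocytes and 5.45 ± 0.45 (SD, n = 8) in leukemias, a change of -3.22 (SE 0.21, adjusted p = 6.5e-07). The transcription factor gene Ets2 fell by 2.88 on the log2 scale, and Ccr9, the receptor for the thymic chemokine Ccl25, by 2.86. Rag2, a subunit of the recombinase that assembles antigen receptor genes, fell by 2.39, and the surface receptor genes Cd5 (log2 change -2.33) and Cd28 (-2.18) fell as well. Further decreases were those of Rmnd5a (log2 change -2.44), the lactate dehydrogenase subunit Ldhb (-2.21), Itm2a (-2.06), Ptov1 (-2.04), the chromatin organizer Satb1 (-1.93) and Ephb6 (-1.93). By the rule that chose them, each of these 12 increases and 12 decreases separated all leukemias from all thymocyte arrays.

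In all, 1429 of 8251 genes changed (17.3%), with 446 higher and 983 lower in leukemia. At least 2-fold changes were more balanced, with 105 genes higher and 114 lower. Over probe sets, 1805 of 12422 changed, 578 higher and 1227 lower. The 8 leukemias lay all above or all below the 4 thymocyte arrays for 1016 genes (12.3%, where chance gives 0.404%), and 961 of these were among the changed genes. The median change over all genes was 0.0037 on the log2 scale. Of the changed genes, 100 lay near the control level in both groups, 38 in thymocytes only and 68 in leukemias only. With arrays with and without a title number of 4 digits as a block, 1624 genes changed. Within the arrays with such a number (4 leukemias, 3 thymocyte arrays) 1459 genes changed, and within the others (4 leukemias, 1 thymocyte array) 4. Leaving out 1 array at a time gave 938 to 1618 genes.

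**Figure D1:**
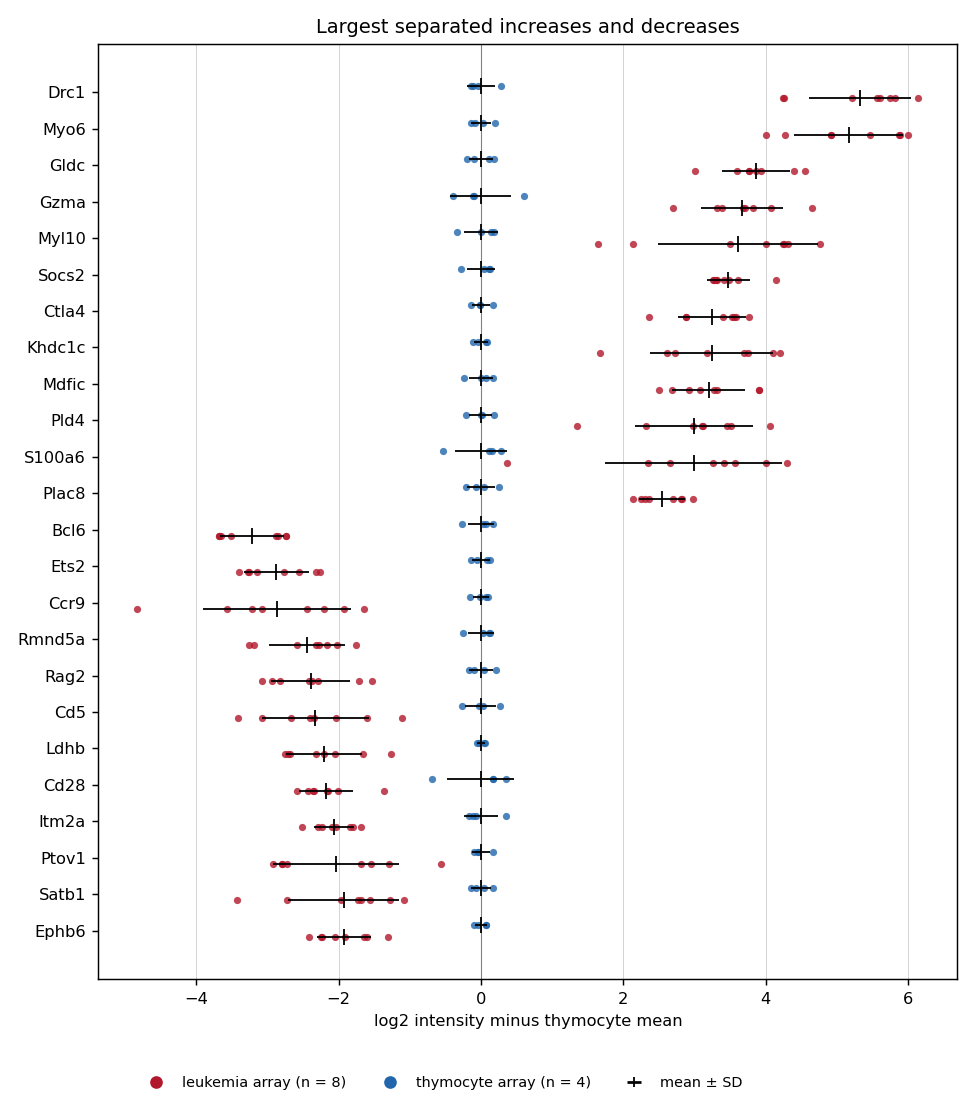
Log2 intensity minus the thymocyte mean for the 12 largest increases and 12 largest decreases. Points are single arrays (red, 8 leukemias; blue, 4 thymocyte arrays) and bars show the mean and SD; the measured mean increases run up to 5.32 for Drc1, whose thymocyte mean lies below the 95th percentile of the controls, and the mean decreases down to -3.22 for Bcl6.

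Of the fusion partners, Jak2 (probe set 101457_at) had log2 values of 6.03, 6.33, 6.24, 6.51, 6.10, 5.56, 6.32 and 5.93 in leukemias 1 to 8 and of 6.86, 6.52, 6.48 and 6.25 in the thymocyte arrays. Its change of -0.40 (SE 0.16) did not pass the test (adjusted p = 0.102). Whether this probe set reads the part of Jak2 kept in the fusion, or the species of the transgene, is not given in the sources used here, so its value does not check the labels. Etv6 was not analysed here.

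The mean score of JAK-STAT target genes was higher in every leukemia than in every thymocyte array. Of 16 members 8 rose, 2 fell and 6 did not pass the test, and adjusted over the list alone 9 rose and 2 fell. Besides Socs2, the feedback inhibitors Cish (log2 change 2.18, SE 0.15) and Socs3 (1.67, SE 0.19) rose, as did the kinase gene Pim1 (0.67), the cyclin gene Ccnd2 (2.00-fold) and the interleukin-2 receptor chains Il2rb (1.78) and Il2ra (at least 3.14-fold, with the thymocyte mean near the control level). The members that fell were Bcl6 and Dusp6, a phosphatase that acts on ERK kinases (at least 2.81-fold lower, near the control level in leukemia). The list had a median change of 0.70 (camera adjusted p = 0.0034, and adjusted p = 0.171 with an estimated correlation). Its mean change was 0.63 over all arrays, 0.66 in arrays with a title number of 4 digits, 0.67 in the others, 0.66 with the block and 0.54 with the score of macrophage markers as a covariate (adjusted p = 0.0066).

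The mean score of MHC class I presentation genes was higher in every leukemia than in every thymocyte array. Of 13 members 11 rose, 0 fell and 2 did not pass, and adjusted over the list alone 12 rose. The light chain gene B2m went from 10.31 ± 0.14 (SD, n = 4) to 11.82 ± 0.11 (SD, n = 8), a 2.84-fold increase. The heavy chain genes H2-D1 (log2 change 1.59, SE 0.14) and H2-K1 (2.83-fold), the immunoproteasome genes Psmb9 (1.33), Psmb10 (1.11) and Psmb8 (0.69) and the peptide transporter gene Tap1 (0.95) rose as well. The H2-D1 and H2-K1 values come from probe sets that can cross-hybridize, as can all 3 probe sets of H2-D1, and a more specific probe set of H2-K1, dim in both groups, gave 0.14 (adjusted p = 0.244 over all probe sets). The list had a median change of 0.80 (camera adjusted p = 7.1e-13, and adjusted p = 0.171 with an estimated correlation) and mean changes of 0.90 over all arrays, 0.89 and 0.94 within the title-number groups, 0.91 with the block and 0.77 with the macrophage score as a covariate (adjusted p = 2.1e-13). Interferon-response genes did not pass the list test (24 members, adjusted p = 0.126), with 7 members up, 3 down and 14 not past the test, and adjusted over the list alone 10 up and 5 down. The risers included Psmb9, Psmb8 and Tap1, which the MHC class I list also holds, and Irf1 (log2 change 1.01), also in the JAK-STAT list. Gbp3 (at least 2.69-fold, near the control level in thymocytes) and Ifi47 (log2 change 1.03) rose as well. Ifit1 (-1.03) and Ifit2 (-0.58) fell near the control level. The interferon score was 0.83, 0.69 and 0.69 in leukemias 3, 5 and 7, which had the highest macrophage scores, and -0.18 to 0.23 in the other 5, separate clusters over which no correlation is given. Across the 8 leukemias the MHC class I score went with the score of macrophage markers (Pearson r = 0.883, exact permutation p = 0.0057, adjusted 0.0171 over 6 pairs; Spearman rho = 0.881, exact p = 0.00724, adjusted 0.0145; r = 0.962 without leukemias 5 and 7, the farthest from the median). The gaps between these scores reached 36.2% of their range, under the limit of 40%, set after the values were seen, for separate clusters. Without leukemias 5 and 7 only leukemia 3 of those with the highest macrophage scores remained, so the r there can rest on it. These relations were looked at after the data were seen, and the 4 leukemias in each title-number group are too few to repeat them within groups.

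Cell division genes were lower in leukemia than in thymocytes. Of 31 mitosis genes 24 fell, 0 rose and 7 did not pass, and adjusted over the list alone 26 fell. Examples are the topoisomerase gene Top2a (log2 change -1.39, SE 0.25), the kinesin gene Kif11 (-1.30, SE 0.19), the cytokinesis gene Ect2 (-1.29, SE 0.15) and the proliferation marker Mki67 (-1.29, SE 0.30). The list's median change was -0.78 (camera adjusted p = 5.3e-12, and adjusted p = 0.498 with an estimated correlation), and the mean score of all 8 leukemias lay below every thymocyte array. Across leukemias the mitosis score had r = -0.320 with the macrophage score (exact permutation p = 0.433, Spearman rho = -0.048, exact p = 0.935). Of 38 DNA replication genes 18 fell and 20 did not pass, and adjusted over the list alone 26 fell and 1 rose. They include the ribonucleotide reductase subunit Rrm2 (-1.72, SE 0.25), the licensing factor Cdc6 (-1.32, SE 0.21) and the sliding clamp gene Pcna (-0.91, SE 0.15), and the list had a median of -0.43 (camera adjusted p = 1.2e-07, and adjusted p = 0.531 with an estimated correlation). Within the title-number groups the mean changes were -0.81 and -0.85 for mitosis genes, with -0.82 under the block and -0.74 over all arrays, and -0.45, -0.54, -0.48 and -0.44 in the same order for DNA replication genes. Among 16 G1 cyclins, CDKs and CDK inhibitors 3 rose and 7 fell, 4 and 7 adjusted over the list alone (adjusted p = 0.148 for the list by camera). The mean score of this list was lower in every leukemia than in every thymocyte array (exact permutation adjusted p = 0.0154). Ccnd3, a D-type cyclin, fell by 1.71 (SE 0.08), and Ccnd2 and the inhibitor gene Cdkn2c (0.61, SE 0.13) rose.

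The mean score of double-positive thymocyte genes, which mark cells with both Cd4 and Cd8 on the surface, was lower in every leukemia. Of 17 members 10 fell, 0 rose and 7 did not pass, and adjusted over the list alone 12 fell. Besides Ets2, Rag2 and Satb1, the coreceptor gene Cd4 (log2 change -1.89, SE 0.31), the semaphorin receptor gene Plxnd1 (-1.67, SE 0.26) and Ptcra, the pre-T-cell receptor chain (-0.96, SE 0.25), fell. The median was -1.18 (camera adjusted p = 1.2e-07, and adjusted p = 0.498 with an estimated correlation), with mean changes of -1.32 over all arrays, -0.89 and -1.67 within the title-number groups, -1.14 with the block and -1.13 with the macrophage score as a covariate (adjusted p = 1.5e-06). The score was -2.56 and -2.15 in leukemias 1 and 7, both without a title number of 4 digits, and -1.21 to -0.65 in the other 6. The early progenitor and double-negative list (19 members) held 1 gene that rose, Il2ra, also adjusted over the list alone (camera adjusted p = 0.0424, adjusted p = 0.498 with an estimated correlation and 0.0696 with the block). Kit, the stem cell factor receptor, had a log2 difference of 0.49 (SE 0.21) and did not pass. In the mature T-cell list (15 members) 5 rose and 2 fell, 6 and 3 adjusted over the list alone (camera adjusted p = 0.0402, adjusted p = 0.539 with an estimated correlation and 0.0605 with the block). Its risers were B2m, H2-D1 and H2-K1, the integrin gene Itgb7 (1.84, SE 0.29) and Ms4a6b (at least 1.12-fold, near the control level in thymocytes), of which the first 3 also belong to the MHC class I list, and Ccr9 and Cd27 fell, the latter on a probe set that can cross-hybridize, where its other probe set gave -0.22 (adjusted p = 0.284 over all probe sets). Mean changes within the title-number groups were 0.21 and 0.29 for the early list and 0.20 and 0.34 for the mature list. With the macrophage score as a covariate the mean of the early list went from 0.24 to 0.16 (adjusted p = 0.153) and that of the mature list from 0.22 to 0.043 (adjusted p = 0.172), and neither passed. The score of the early list passed an exact permutation (adjusted p = 0.032) and that of the mature list did not (adjusted p = 0.228).

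The mean score of cytotoxic effector genes was higher in every leukemia than in every thymocyte array, with a wide range. Of 20 members 3 rose, 0 fell and 17 did not pass, with the same count adjusted over the list alone. They were Gzma (log2 change 3.67, SE 0.29), the granzyme inhibitor gene Serpinb9 (1.38, SE 0.31) and Il2rb (1.78, SE 0.47). In leukemias 1, 3, 5 and 7 Gzma was at 10.41, 11.10, 11.40 and 11.42. In leukemias 2, 4, 6 and 8 Gzma was at 11.79, 11.54, 11.03 and 12.36, against a thymocyte mean of 7.71. Gzmb was at 6.38, 6.23, 5.88 and 7.97 there, against 5.74 to 6.13 in thymocyte arrays. The score without Gzma, whose probe set can cross-hybridize, was not computed. The list had a median of 0.37 and a mean of 0.83 (camera adjusted p = 0.00045, and adjusted p = 0.531 with an estimated correlation), with means of 0.69 and 0.98 within the title-number groups and 0.79 with the block. With the macrophage score as a covariate the mean was 0.50 (adjusted p = 0.0242). The score of NK cell markers was 0.68, 0.55, 0.71 and 1.02 in leukemias 1, 3, 5 and 7, where the cytotoxic score was 1.13 to 1.54, and 0.24, -0.22, 0.05 and 0.03 in leukemias 2, 4, 6 and 8, where it was 0.18 to 0.60. Across the 8 leukemias the cytotoxic score went with that of macrophage markers (Pearson r = 0.784, exact permutation p = 0.0304, adjusted 0.0456 over 6 pairs; Spearman rho = 0.881, exact p = 0.00724, adjusted 0.0145; r = 0.692 without leukemias 5 and 7), with gaps between scores of up to 38.8% of their range. Leaving out leukemias 5 and 7 kept only leukemia 3 of those with the highest macrophage scores, so the r there can rest on it. With the macrophage covariate Il2rb no longer passed the test (1.32).

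T-cell receptor complex and proximal signalling genes moved both ways. Of 26 members 4 rose and 5 fell, also adjusted over the list alone (adjusted p = 0.407 for the list by camera). Its score was below every thymocyte array in 7 of 8 leukemias (exact permutation adjusted p = 0.0384). The adhesion receptor gene Cd2 rose by 1.38 (SE 0.11), with the kinase gene Fyn (0.57, SE 0.14), whereas Cd6 (-1.32, SE 0.11), Cd247, the zeta chain (-0.93, SE 0.15), Cd5 and Cd28 fell. Among 16 calcineurin-NFAT and receptor early-response genes 5 fell and 1 rose, also adjusted over the list alone (adjusted p = 0.0726, 0.539 with an estimated correlation, 0.00541 with the macrophage covariate and 0.0256 by exact permutation of the score). The transcription factor genes Egr1 (-1.54, SE 0.15), Egr2 (-1.21, SE 0.17) and Nr4a1 (-1.07, SE 0.15) and the calcineurin regulator Rcan1 (-0.59, SE 0.07) fell. Of 19 immediate-early and heat-shock genes, which respond to handling, 5 fell, also adjusted over the list alone (adjusted p = 0.126, 0.525 with an estimated correlation, 0.0267 with the macrophage covariate and 0.0154 by exact permutation), among them Egr1, Zfp36 (-0.87) and Hsph1 (-0.99).

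Cell death genes also moved in both directions. Of 18 BCL2-family and caspase genes 3 rose and 3 fell, also adjusted over the list alone (adjusted p = 0.418, and 0.0279 by exact permutation of the score, higher in leukemia). Bcl2, which opposes apoptosis, rose 4.79-fold (log2 change 2.26, SE 0.20), and the pro-apoptotic gene Bcl2l11 rose by 0.79 (SE 0.15), while Bid fell (-0.39). The measured decrease of Bcl2l2 (-0.54), counted here, lies near the control level, where its lower bound of 0.984-fold allows no decrease. Of 13 p53 target genes 2 rose and 4 fell, 2 and 5 adjusted over the list alone (adjusted p = 0.258, and 0.0279 by exact permutation of the score, lower in leukemia), with decreases of the death receptor gene Fas (at least 2.00-fold, near the control level in leukemia), Sesn1 (log2 change -1.12), Gadd45a (-0.69) and Mdm2 (-0.62). The members that rose were Cdkn1a (log2 change 0.32) and Ccng1 (at least 1.32-fold, near the control level in thymocytes). NF-kappaB target genes (22 members) had 2 up and 2 down, 3 and 2 adjusted over the list alone (adjusted p = 0.126). Ltb rose by 0.88 (SE 0.11), and Lta by 0.63 on a probe set that can cross-hybridize, where its other probe set gave -0.0385 (adjusted p = 0.892 over all probe sets). The inhibitor genes Nfkbia (-0.57) and Tnfaip3 (-0.66) fell. Notch target genes (13 members) had 3 up and 1 down, also adjusted over the list alone (adjusted p = 0.115), with Lfng, a glycosyltransferase that modifies Notch, up by 1.08 (SE 0.16). Among 28 T-cell leukemia oncogenes and tumour suppressors 2 rose and 3 fell, also adjusted over the list alone (adjusted p = 0.936). The kinase gene Jak3 (1.05, SE 0.21) and the phosphatase gene Ptpn2 (0.55, SE 0.10) rose, and the Polycomb gene Ezh2 (-0.96, SE 0.18) and Lef1 (-0.82, SE 0.15) fell.

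Of 15 glycolysis genes 4 rose, 1 fell and 10 did not pass, with the same count adjusted over the list alone. Aldoa (log2 change 0.83, SE 0.13), Hk1 (0.47, SE 0.07), Pkm (0.36) and Ldha (0.32), all enzymes of the pathway or its end step, rose, and the lactate transporter gene Slc16a1 (-0.99) fell near the control level. The median was 0.19 (camera adjusted p = 0.0402, adjusted p = 0.539 with an estimated correlation and 0.0717 with the block), and the mean changes within the title-number groups were 0.12 and 0.18. With the macrophage score as a covariate the mean went from 0.16 to 0.067 and did not pass (adjusted p = 0.263), nor did the score pass an exact permutation (adjusted p = 0.197), with 6 leukemias above and 1 below every thymocyte array. The citrate cycle and respiratory chain list (28 members) had 1 up and 2 down, also adjusted over the list alone (adjusted p = 0.956), with Cox5b at 0.37 and Ogdh at -0.23. Sterol and fatty-acid synthesis genes (18 members) had 2 up and 0 down, also adjusted over the list alone (adjusted p = 0.131, 0.644 with an estimated correlation, 0.0064 with the macrophage covariate and 0.305 by exact permutation), namely Mvd (1.04) and Elovl6 (0.46). Myc target and ribosome-biogenesis genes (30 members) had 3 up and 3 down, 3 and 4 adjusted over the list alone (adjusted p = 0.967), with Nme2 at 0.88 and Hspd1 at -0.51. Of 20 homing and adhesion genes 3 rose and 5 fell, 4 and 5 adjusted over the list alone (adjusted p = 0.587). Selplg, the selectin ligand, rose by 1.01 (SE 0.08) with Itgb7 and Itgae (1.32), and the chemokine receptor gene Cxcr4 (-1.31, SE 0.21), Icam2 (-1.17) and Itgb1 (-1.21) fell; the list's median was 0.069, its mean -0.018, and its test pointed up.

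**Figure D2:**
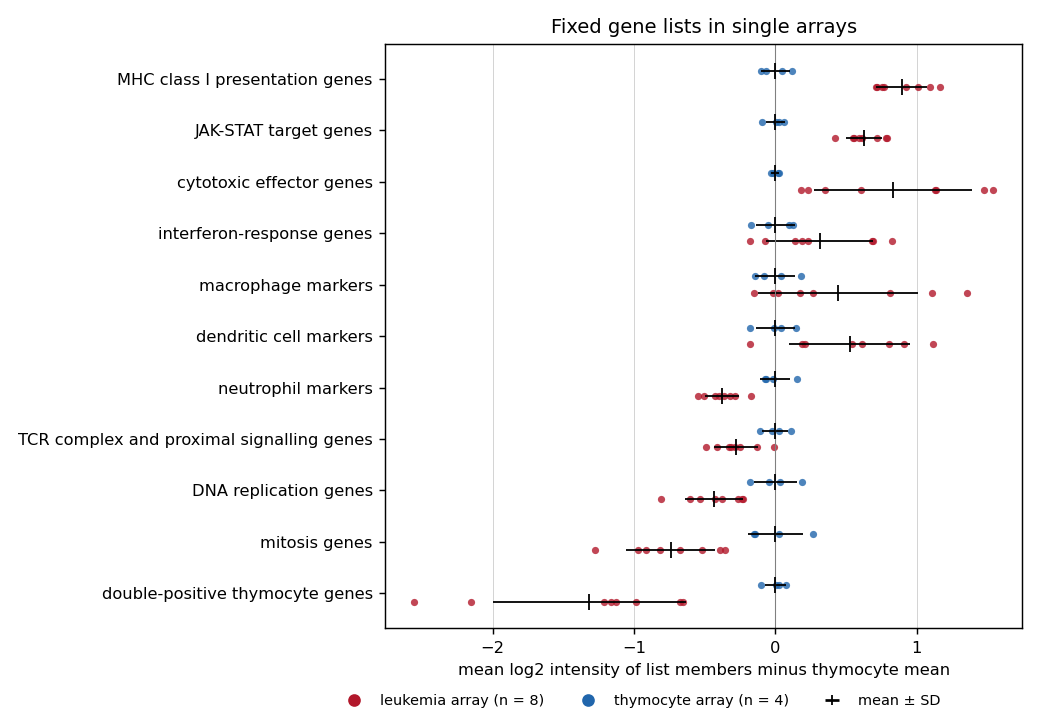
Mean log2 intensity of the members of 11 gene lists minus the thymocyte mean, one point per array (red, 8 leukemias; blue, 4 thymocyte arrays), with bars for the mean and SD. Mitosis genes averaged -0.74 and double-positive thymocyte genes -1.32 in leukemia, and the macrophage and cytotoxic scores spread widely between leukemias.

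Markers of other cells gave the following values. Macrophage markers (16 members) had no single gene past the test, also adjusted over the list alone (3 at an unadjusted p under 0.05 by limma), and a median of 0.34, with C1qc at 0.63 (SE 0.49) and Ctsb at 0.34 (SE 0.13). The list passed camera (adjusted p = 0.0132, and adjusted p = 0.539 with an estimated correlation), with mean changes of 0.45 over all arrays, 0.44 and 0.55 within the title-number groups and 0.47 with the block. Its score did not pass an exact permutation (adjusted p = 0.227). It was 1.35 in leukemia 7, 1.11 in leukemia 5 and 0.81 in leukemia 3, and between -0.15 and 0.27 in the other leukemias. Dendritic cell markers (10 members, adjusted p = 0.0532, 0.539 with an estimated correlation, 0.0889 by exact permutation, and 0.0471 with the block, where they passed) and B cell markers (11, adjusted p = 0.115) did not pass, with H2-Aa at 1.32 (SE 0.45), Cd74 at 1.16 (SE 0.38) and Cd79a at 0.70 (SE 0.25), and neither did markers of plasma cells (5, 0.275), NK cells (5, 0.126), gamma-delta T cells (2, 0.228), platelets (5, 0.228), mast cells (6, 0.542) or adipocytes (5, 0.407). None of these 8 lists held a gene past the limma test, over all genes or adjusted over the list alone, and 12 of their 49 members had an unadjusted p under 0.05. Neutrophil markers (11 members, adjusted p = 0.0601) had 4 that fell, 5 adjusted over the list alone, with S100a8 at -1.66 (SE 0.22), Camp at -0.49, and Ngp and S100a9 at least 1.49-fold and 1.29-fold lower, both near the control level in leukemia. The list passed with the block (adjusted p = 0.0471), with the macrophage covariate (adjusted p = 0.0117) and by exact permutation (adjusted p = 0.0154), but not with an estimated correlation (adjusted p = 0.525). In thymic epithelium markers (9, adjusted p = 0.536) Ccl25 (at least 2.03-fold, near the control level in leukemia) and Krt18 (log2 change -0.40) fell and Epcam (1.37, SE 0.26) rose, the latter pair near the control level in both groups, with the same count adjusted over the list alone. Erythroid markers (8, adjusted p = 0.739) had Gata1 up by 0.69 and Car2 at least 1.65-fold lower, near the control level in leukemia, also adjusted over the list alone, and Hba-a1 at -0.81 (SE 0.47) without passing. Endothelium markers (9, adjusted p = 0.542) had Eng at -0.38, which did not pass adjusted over the list alone. Fibroblast markers (13, adjusted p = 0.966) had Postn at -0.37, near the control level, also adjusted over the list alone, with a median of 0.041, a mean of -0.017 and a test pointing down. Sex-linked genes (4, adjusted p = 0.678) had no member past the test, and Xist ranged from 3.60 to 7.33 in leukemias and from 3.46 to 8.36 in thymocyte arrays. The 3' minus 5' difference of the control probe sets was -0.20 to 0.06 for Gapdh and 0.36 to 0.59 for actin over the 12 arrays.

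Of the 38 lists 10 passed camera, 7 higher and 3 lower in leukemia, and 0 passed with an estimated correlation, where 2 had an unadjusted p under 0.05. Leaving out 1 array at a time gave 6 to 13 lists, the fewest without thymocyte array 4 (3 higher and 3 lower), and the macrophage covariate gave 4 higher and 6 lower. By fry 15 passed, by exact permutation of the scores 14, of which 7 are among these 10, and in 24 of 100 splits of the 12 arrays into 8 and 4 at least 10 lists passed camera.

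The spread between arrays was compared to see whether leukemias differ among themselves more than thymocyte samples do. Leukemias lay 0.290 ± 0.057 log2 units (SD, n = 8) from the mean of the other leukemias, and thymocyte arrays 0.168 ± 0.046 (SD, n = 4) from the mean of the other thymocyte arrays, a ratio of 1.73 (exact permutation p = 0.00606, two-sided, over 495 assignments). The shuffled distances share arrays within a group and were taken from means of 7 leukemias or 3 thymocyte arrays. They are thus not fully exchangeable, and the p-values for the spread are approximate. Of the 8 leukemias 7 lay farther from their group than every thymocyte array did from its own. Within the arrays with a title number of 4 digits (4 leukemias, 3 thymocyte arrays) the ratio was 1.73 (exact permutation p = 0.0286, the smallest possible), and the other title-number group has only 1 thymocyte array. The labels do not say whether thymocyte array 4, whose title has no number, holds 1 animal or several, and without it the ratio was 1.99. Among genes other than receptor segments, Gzmb, singled out after the values were seen, had the largest SD between leukemias, at 2.67, against 0.19 between thymocyte arrays. With 4 leukemias drawn to match the 4 thymocyte arrays the ratio ran from 1.42 to 2.23, and 45 of 70 such subsets passed the exact test, whose smallest possible p is 0.0286. The subsets share leukemias and all use the same 4 thymocyte arrays, so they are not separate tests.

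T-cell receptor gamma chain segments were higher in all or nearly all leukemias, and some beta chain probe sets differed between single leukemias. Of 13 probe sets 4 had a leukemia at least 2 log2 units above the thymocyte mean, and 6 at least 1 unit. Trgv1 (102695_at), a gamma chain segment, was that high in all 8 leukemias, at 11.60 ± 0.36 (SD, n = 8) against 7.90 ± 0.35 (SD, n = 4), and so was the probe set shared by Trgv4 and Trgv2 (102744_at), at 11.95 ± 0.62 against 8.80 ± 0.38. Trgv4 (102745_at) was that high in 7 of 8 leukemias and stood at 9.02 in leukemia 1. The mean score of the 2 gamma-delta T cell markers analysed, Blk and Sox13, also lay above every thymocyte array in all 8 leukemias. Neither gene passed the test (log2 changes 0.88, SE 0.37, and 0.21, SE 0.13), and the list did not pass camera (adjusted p = 0.228). Trbv1 (94726_at), a beta chain segment, was at 12.92 in leukemia 3 and between 6.16 and 6.63 in the other 7 leukemias, against a thymocyte mean of 9.77, but another Trbv1 probe set (93105_s_at) was at 12.69 to 13.41 in all 8 leukemias. Trbv13-2 (101279_f_at) was at 11.59, 10.74, 11.93 and 11.89 in leukemias 1, 5, 6 and 7 and at 6.98, 5.62, 7.82 and 6.49 in leukemias 2, 3, 4 and 8, against a thymocyte mean of 10.17. The other Trbv13-2 probe set (94202_at) ran differently, at 5.50, 7.67, 6.64 and 5.02 in leukemias 1, 5, 6 and 7 and at 7.26, 5.37, 7.56 and 6.30 in leukemias 2, 3, 4 and 8, all below its thymocyte mean of 8.35, so these values do not settle which leukemias carry this segment. Across the probe sets, 3 had a leukemia at least 2 log2 units below the thymocyte mean. Probe sets whose names end in letters before "at" can read related segments.

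**Figure D3:**
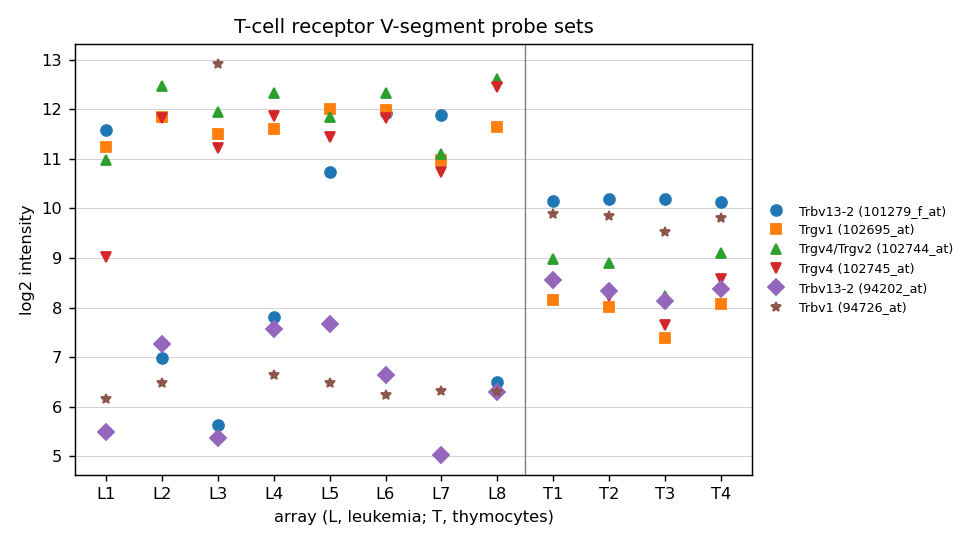
Log2 intensity of 6 T-cell receptor variable-segment probe sets in each of the 8 leukemias (L) and 4 thymocyte arrays (T), one symbol per probe set. Trbv1 (94726_at) reached 12.92 in leukemia 3 and lay below the thymocyte mean of 9.77 in the other 7 leukemias.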

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

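The tests of a batch shared by both groups and of chromosome 18 as its source were chosen only after the result was seen, and the search for arrays far from their group and for chromosome-wide shifts was planned.

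Single arrays far from the rest of their group were found for 16 of 380 results tested, where chance gives about 19, by the gap to the nearest array relative to the range of the group. Of these, 9 were in leukemias and 7 in thymocyte arrays, 4 of the latter in thymocyte array 4 and 3 in thymocyte array 3. The values are log2 distances from the median of the other arrays of the group. The farthest was Trbv1 (94726_at), 6.62 higher in leukemia 3. Trav12n-1 (93223_at) was 1.73 higher in leukemia 4, and Trgv1 (102695_at) was -0.68 from the others in thymocyte array 3. Cd28 was 0.99 higher and Ect2 0.71 higher in leukemia 2. Socs2 was 0.84 higher in leukemia 1, and Retn 0.26 higher in leukemia 8. In leukemia 7, Lef1 stood at -0.81, the score of BCL2-family and caspase genes at -0.17 and the Gapdh 3' minus 5' difference at 0.15. In thymocyte array 4, Plxnd1 stood at -0.76, Pecam1 at 0.22, Thy1 at 0.18 and Fcer1g at 0.16. In thymocyte array 3, Bid stood at -0.32 and Pkm at -0.11.

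Arrays without a title number of 4 digits, leukemias 1, 6, 7 and 8 and thymocyte array 4, differed from the others partly alike in both groups. Among these leukemias, 6 and 8 correlated at 0.989 and 1 and 7 at 0.988. They did not all stand together, since leukemia 8 correlated with leukemias 1 and 7 at only 0.979 and 0.975. With leukemias 2, 3 and 4 it correlated at 0.986 to 0.989. Gene by gene, the mean difference of the arrays without such a number from the others of their group correlated between leukemias and thymocytes (r = 0.543). The 8251 genes are not independent replicates, and 2 of 70 splits of the leukemias into 4 and 4 gave an r as high (exact p = 0.0286, one-sided). On the thymocyte side this is 1 array against 3, and the splits shuffled only leukemias. The p-value therefore does not show that the thymocyte difference exceeds that array's own deviation. Xist also differed alike in both groups, so a batch shared by both groups, a possible source, is not separated from sex. Among genes above the median brightness, those of chromosome 18 were lower in these 5 arrays relative to the array median (-0.24, -0.13, -0.21 and -0.13 in leukemias 1, 6, 7 and 8 and -0.16 in thymocyte array 4), but without the genes of chromosome 18 the r was 0.541, which argues against those genes alone. Genes lower in these arrays in both groups included Nrip1 (-1.14 in leukemias, -1.82 in thymocytes), Med1 (-1.01 and -1.55) and Xist (-2.06 and -1.72). Xist was at 6.19 to 7.33 in leukemias 2, 3, 4 and 7, where the Y-linked Eif2s3y was at 3.72 to 4.32. In leukemias 1, 5, 6 and 8 Xist was at 3.60 to 4.08 and Eif2s3y at 6.38 to 7.62. The female pattern was thus more frequent among leukemias with a 4-digit title number, and only leukemia 7 showed it without one. The labels give no biological difference between these arrays, and none was tested.

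Over genes above the median brightness, chromosome-wide shifts passed the test in 5 of 160 pairs of leukemia and chromosome and in 6 of 80 pairs in thymocyte arrays, which serve as the control. In leukemias 4 of the 5 were on chromosome 18, and the other was chromosome 2 in leukemia 6 (0.085). Over all genes 0 of the 160 and 3 of the 80 pairs passed, with 15 and 19 at an unadjusted p under 0.05, and the largest shift of any chromosome in a leukemia was 0.062. Leukemias were measured against the mean of all 4 thymocyte arrays, and each thymocyte array against the other 3. A shift in 1 thymocyte array thus moves the others the opposite way, as on chromosome 18 (-0.16 in array 4, 0.096 in array 1). The control count is therefore not on equal terms with that of the leukemias.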

How the results depend on the processing

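The title-number block, the arrays without a title number of 4 digits alone, the macrophage score as a covariate and the spread within the arrays with such a number (1.73) were chosen only after the result was seen, and the other alternatives before. No paired analysis was possible because the labels give no replicate numbers shared by the groups. Leaving out each array in turn gave 1162 to 2044 probe sets (390 to 618 higher, 759 to 1426 lower), 938 to 1618 genes (304 to 483 higher, 626 to 1135 lower), 6 to 13 lists (3 to 9 higher, 3 to 5 lower) and a spread ratio of 1.41 to 1.99 (highest exact p 0.0485). Without thymocyte array 1 there were 1162 probe sets, with 759 lower, and 938 genes, with 626 lower, and without thymocyte array 2 there were 1185 probe sets, with 792 lower, and 655 genes lower. The lists higher in leukemia were 4 without leukemia 1, 5 or 7 or thymocyte array 3, and 3 of 6 lists without thymocyte array 4, and the lists lower were 5 without leukemia 7. The arrays without a title number of 4 digits alone gave 13 probe sets (3 higher, 10 lower) and 4 genes (1 higher, 3 lower), from fewer arrays, with the single thymocyte array assumed to vary like the leukemias. A threshold of 0.01 left 1008 probe sets (333 higher, 675 lower), and treat against 1.5-fold left 128 (80 higher, 48 lower), both stricter by construction. The lists higher were 4 after quantile normalization, 4 in arrays with a title number of 4 digits, 4 with the macrophage covariate and 4 with members of only 1 list. The lists lower were 6 with the macrophage covariate and 8 by fry, and camera with an estimated correlation gave 0 in all, 0 higher and 0 lower, with 2 at an unadjusted p under 0.05, where fry gave 15. The cause was not tested except where stated. Chromosome-wide shifts in leukemias numbered 5, against 0 with all genes (15 at an unadjusted p under 0.05) and 9 without genes changed between the groups. The segment count of 4 was 6 at 1 log2 unit and 4 at 3 units. Lta went to -0.0385 without cross-hybridizing probe sets, which leaves another probe set of the gene. A change of sign was counted as reversed only where one of the values passed the threshold, and 82 signs differed with neither past it. For named genes, 3021 comparisons counted as unchanged, 176 lost the call, 29 gained it and 1 reversed. For lists, 863 counted as unchanged, 48 lost the call, 34 gained it and 0 reversed. The 82 differing signs lie within the counts called unchanged. Signal over background limits the 100 changed genes near the control level, whose values lie close to background.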

Other observations

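The tests of explanations for the mitosis and cytotoxic patterns and the exact permutation of list scores were chosen only after the result was seen, the counts over other splits of the arrays were planned, and the genes in the next paragraphs were chosen after their values were seen.

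Several genes of T-cell function differed widely between leukemias. Gzmb, a protease of cytotoxic granules, had log2 values of 11.09, 6.38, 11.42, 6.23, 11.02, 5.88, 12.22 and 7.97 in leukemias 1 to 8, and 5.74 to 6.13 in thymocyte arrays. Ccl5, a chemokine of activated T cells, was at 11.74, 6.95, 9.99, 5.88, 10.32, 6.35, 11.03 and 7.80 in the same order, against 6.39 to 7.12. Rag1, the partner of Rag2 in the recombinase, was at 4.86 in leukemia 1 and 7.99 in leukemia 7, at 9.93 to 11.06 in the other 6, and at 11.83 to 11.99 in thymocyte arrays. Cd7, a T-lineage surface protein, ranged from 6.49 in leukemia 6 to 10.72 in leukemia 1.

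Genes of other lineages also varied. Jchain, which links the units of polymeric antibodies, was at 10.67 in leukemia 2 and 10.22 in leukemia 4, at 5.78 to 6.71 in the other leukemias and at 4.93 to 5.39 in thymocyte arrays. Arg1, an enzyme of macrophages, was at 6.96, 7.60 and 6.67 in leukemias 3, 5 and 7, the arrays with the 3 highest macrophage scores, and at 3.55 to 4.17 in the other 5. The interferon-induced chemokine gene Cxcl9 was at 7.08, 6.59 and 7.43 in the same 3 leukemias, and the interferon-induced GTPase gene Iigp1 at 9.02, 8.87 and 9.02. Xist was at 4.95 and the Y-linked Eif2s3y at 4.90 in thymocyte array 4, between the levels of thymocyte arrays 1 and 2 (8.21 and 8.36 for Xist, 3.52 and 3.86 for Eif2s3y) and of thymocyte array 3 (3.46 and 6.78).

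The number of changed genes was set against other splits of the 12 arrays into 8 and 4. Of 100 splits, only 1, the real one, gave as many as 1429 genes, with 394 the highest of the others. The same held for 1805 probe sets, with 514 the highest of the others. The smallest share that such a draw can show is 1 of 100. Splits that mix leukemias and thymocyte arrays count the group difference as spread within groups, which lowers their counts. Both counts exceeded those of every other split drawn, and chance is not excluded beyond that. For the 10 lists, 24 of 100 splits gave as many, with 17 the highest of the others, so chance cannot be excluded for their number. An exact permutation of each list's mean score over 495 assignments, adjusted over the lists, passed 14 lists, 7 of them among the 10 called by camera.

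Mitosis genes fell in leukemia, which a technical shift could produce. Array scaling alone would move all genes, and the median change over all genes was 0.0037 with a median absolute deviation of 0.126. The deposited arrays already had closely similar medians (66.48 to 70.18), which fixed a small median change beforehand. The values therefore hold no shift common to all genes. They cannot show what the processing before deposit did to mitosis genes. With the macrophage marker score in the model the group difference of the mitosis score was -0.65 (SE 0.19) against -0.74 (SE 0.17) without it, which argues against cells counted by those markers as the whole source. With the title-number groups in the model it was -0.82 (SE 0.15), which argues against that batch. The groups also differ in disease, and the age of the leukemic mice is not given in the sources used here, so a biological source stays open as untested.

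Cytotoxic genes differed between leukemias, and other cells in the samples are a candidate source. The cytotoxic score went with the macrophage score at r = 0.784 over the 8 leukemias (exact permutation p = 0.0304), as infiltrating cells would give. The relation rests on scores with gaps of up to 38.8% of their range, just under the limit of 40% set after the values were seen, above which 3 of the 6 pairs were left out as separate clusters. Leukemias with a title number of 4 digits alone spanned 69.9% of the range of the cytotoxic score, which argues against a batch as the whole source. Gzma, on a probe set that can cross-hybridize, was not highest where the macrophage score was highest. It was at 10.41, 11.10, 11.40 and 11.42 in leukemias 1, 3, 5 and 7. In leukemias 2, 4, 6 and 8 it was at 11.79, 11.54, 11.03 and 12.36, against a thymocyte mean of 7.71. Whether the leukemic cells themselves carry these transcripts stays open: leukemia 1 combined a cytotoxic score of 1.48 with a macrophage score of 0.27 but an NK marker score of 0.68, in a list of 5 genes that includes Tyrobp and Fcer1g, also expressed by macrophages, and Klrd1, which the cytotoxic list also holds.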
